A study of Homo sapiens with 8 samples.

How the data were processed

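RNA was analysed from samples labelled as γδ T cells of 4 donors, each with 1 shControl and 1 shPERK library (8 libraries). Per the labels' protocols, T cells were expanded from blood mononuclear cells, transduced with lentivirus, kept for 48 hours with myeloid, endothelial and tumour cells and isolated with CD3 beads. Messenger RNA was enriched with oligo(dT) and made into libraries with a kit that includes PCR. The submitters' processing notes name kallisto 0.46.1, R 4.0.5, edgeR without a version and the genome build GRCh38, with no role or order. The gene annotation and the read strand setting are not given in the sources used here, so transcripts of overlapping or near-identical genes may share values.

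Of the 3 deposited tables, 2 were used. The first holds log2 values, which per the file headers are log2 CPM, filtered and normalized over all samples by the authors. The second holds a signal that the authors deposited as CPM values. On testing, it equalled 2 to the power of the deposited log2 CPM, with the same lowest value, 0.1048, in every library, so a prior count is still in it, and its columns summed to 818304 to 1100324. It is called normalized CPM throughout. A further table of log2 CPM was not used here because 4 of its columns are named for donors E and F, letters that no sample label has, while none is named for donors C and D. The letters C and D therefore rest on the labels and the 2 tables used, and whether they were reassigned is not known. In all, 16 columns of per-sample values were not used. The design fixed before the data were examined had assumed plain CPM, and the same test on the log scale was kept for the normalized values. Low values were not whole multiples of a step, so reads could not be recovered and the depth of each library is unknown. The number of genes at the lowest value was 23, 55, 321 and 654 in the shControl libraries of donors A to D and 15, 21, 17 and 37 in the shPERK libraries.

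Of 13473 genes, 18 on the Y chromosome or of X inactivation were left out of every step, which left 13455. Genes with at least 1 normalized CPM in at least 4 libraries were tested (13450). Values were taken as log2(CPM + 0.5), and a difference is shPERK minus shControl on that scale, which understates the change of genes with low values. Each gene was tested with limma 3.58.1 in R 4.3.3, with a linear model of the arm over all 8 libraries, moderated variance with a trend, two-sided p-values, Benjamini-Hochberg adjustment and a threshold of 0.05. Coordinates came from GENCODE release 29 on GRCh38, matched by symbol for 12919 genes. Means are given with the SD over the 4 libraries of an arm. EIF2AK3 and the other 3 eIF2α kinases also had an exact permutation test over 70 arrangements and an exact sign-flip test of the donor differences over 16. Tables were joined with Python 3.11.15 and pandas 2.3.3.

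Before the data were examined, 30 gene lists with 729 entries were fixed, of which 643 were matched by symbol. They covered the integrated stress response, chaperones and ER-associated degradation, cytotoxic, inhibitory, memory, activation and cytokine genes, nuclear and mitochondrial respiratory genes, mitochondrial biogenesis, glycolysis, the tricarboxylic acid cycle with fatty acid oxidation, antioxidant, cell cycle, interferon, apoptosis, NF-κB, hypoxia, cholesterol, immediate early, ribosomal and γδ T cell identity genes, and markers of αβ T, myeloid, endothelial, epithelial, mesenchymal, B, natural killer, erythroid and platelet cells. No aminoacyl-tRNA synthetase of the integrated stress response list and no ATP synthase subunit of the nuclear respiratory list was matched. These families were not tested, and whether they are absent or stand under other symbols was not examined. The 27 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01 and adjustment over the lists. With the correlation estimated from the data, 0 of the 16 lists that passed held, and fry, which asks whether the genes of a list move on balance in 1 direction, called 0 (smallest adjusted p 0.0815). Its test of change in either direction, which compares a list with no other genes, was not among the tests fixed beforehand.

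The named genes followed a rule fixed before the data were examined. It took EIF2AK3, the other eIF2α kinases, ATF4, DDIT3, HSPA5 and XBP1. In each direction it took up to 12 genes past the threshold, with the largest differences, the same direction in all 4 donors and a mean of at least 5 normalized CPM. Short directions were filled from the fit with a donor block, and then by its smallest unadjusted p, given as not past the threshold. From each list it took the 3 members with the smallest p. HLA genes, receptor variable segments and genes with clone names were not named. The rule gave 101 genes, of which the text prints a part, and some results are not reported here.

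The labels give the donor letter, so the libraries are paired by donor. As a check, the deviations from the arm means were correlated over all genes between libraries of the same donor, which gave -0.005, -0.107, -0.191 and -0.159 for donors A to D. Between libraries of different donors they ran from -0.391 to 0.324, so libraries of the same donor were no more alike in this check. A fit with the donor as a block was chosen before the data were examined, and its value stands beside a result where it changed the call. The other settings chosen then were pseudocounts of 0.1 and 2, the deposited log2 values, no filter and a minimum of 5, quantile normalization, median centring, variance moderation without the trend or robust, array weights, the donor as a random effect, the block with quantile normalization, a minimum difference of 1, and leaving out each library or donor. After seeing the data, 3 were added. They left out the shControl libraries of donors C and D, left out those of donors A and B, or used the mean log2 level of 8 T cell genes as a covariate (the T cell score, from CD3D, CD3E, CD3G, CD247, CD2, LCK, ZAP70 and LAT). Count models were not used, since no counts were available.

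The limma step was tested on simulated data for the comparison of shPERK with shControl, with 13450 genes and 50 genes changed per size. At the observed spread it recovered 12% of genes changed by 1 log2 unit, 38% by 2, 64% by 3 and 70% by 4, with 10 false calls and 0 of wrong sign. A simulated list shifted by 1 log2 unit had a camera adjusted p of 4.26e-24, and 0 of the unshifted lists were called. The simulated genes were drawn independently, whereas the estimated correlation was 0.399 in the chaperone, 0.705 in the myeloid and 0.952 in the mitochondrial list. The simulation therefore cannot show false list calls that arise from correlated genes. It also drew both arms with the same SD for a gene. In the data the SD of the mesenchymal list mean was 3.47 in shControl and 0.41 in shPERK, and that of the mitochondrial list mean 0.57 and 1.04. The effect of unequal spread on the calls was not simulated.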

Results

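Gene expression was measured by RNA sequencing in samples that the labels name as human γδ T cells, lymphocytes whose antigen receptor is built from a γ and a δ chain. The cells had been expanded from blood mononuclear cells of 4 healthy donors, named A to D. Each donor's cells received by lentivirus either a control short hairpin RNA (shControl) or a hairpin against PERK (shPERK). This gave 2 arms of 4 libraries each. PERK, encoded by EIF2AK3, is a kinase of the endoplasmic reticulum that senses unfolded protein and phosphorylates the translation factor eIF2α. After transduction the cells spent 48 hours with myeloid, endothelial and tumour cells, an in vitro model of the tumour microenvironment. They were then pulled out with magnetic beads against CD3, a surface protein of T cells. The values were normalized CPM (counts scaled to library size) for 13473 genes. Read depth is unknown, because no counts were available. The normalized values of these 13473 genes summed to between 818304 in the shControl library of donor C and 1100324 in the shPERK library of donor D. The comparison of the arms asked which transcripts differed when PERK was knocked down in T cells exposed to these other cells.

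EIF2AK3, the gene targeted by the hairpin, fell in shPERK to 20.4% of its shControl mean, from 50.2 ± 6.50 to 10.2 ± 1.07 normalized CPM (SD, n = 4 per arm). PPP1R15A, which encodes the stress-induced GADD34 subunit that directs dephosphorylation of eIF2α, fell from 559 ± 90.8 to 88.6 ± 22.2 normalized CPM. CDK2AP2, which encodes a cyclin-dependent kinase 2 associated protein, fell from 240 ± 24.5 to 79.8 ± 8.36. TUBA1A, an α-tubulin gene, rose from 87.3 ± 12.1 to 397 ± 81.1. MARCKSL1, which encodes an actin-regulating protein, rose from 35.4 ± 8.70 to 154 ± 15.2. ENG (endoglin, a co-receptor for TGF-β), CD248 (endosialin, a surface protein of fibroblasts and pericytes) and NRGN (the calmodulin-binding protein neurogranin) also rose. With the donor as a block none of these genes passed in limma (adjusted p = 0.146 for each). The libraries also differed in transcripts of other cells. COL1A1, a mesenchymal marker, stood at 2630, 307, 0.376 and 1.84 normalized CPM in the shControl libraries of donors A to D and between 2450 and 4143 in shPERK. For the genes that rose, a change within T cells therefore cannot be told apart from a difference in cell content.

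In single libraries EIF2AK3 stood at 47.1, 56.8, 42.7 and 54.3 normalized CPM in the shControl libraries of donors A, B, C and D. It stood at 11.5, 10.4, 10.2 and 8.86 in the shPERK libraries of the same donors. The log2 difference was -2.24 (SE 0.23, limma adjusted p = 0.0217), a 4.72-fold decrease. It lay between -2.549 and -1.995 in the 4 donors. The exact permutation test of the 8 values gave p = 0.0286, two-sided, the smallest that 70 arrangements allow, and 0.0572 after Benjamini-Hochberg adjustment over the 4 eIF2α kinases. The exact sign-flip test of the 4 donor differences gave p = 0.125, the smallest that 16 arrangements allow. EIF2AK3 lies on chromosome 2 at 88556741 to 88627576 on the minus strand (GRCh38, GENCODE release 29), and its value sums the transcripts of the whole gene. EIF2AK4 had the same exact p values (0.0286, 0.0572 and 0.125) in the other direction, higher in shPERK in all 4 donors (146% of its shControl mean). The other eIF2α kinases did not pass in limma. EIF2AK2 had a log2 difference of -0.45 (adjusted p = 0.333), EIF2AK4 of 0.56 (0.197) and EIF2AK1 of -0.03 (0.963), a sign that turned when single libraries were left out. With the donor as a block, the EIF2AK3 difference was again -2.24, with a limma adjusted p of 0.146. Leaving out any 1 library kept it between -2.31 and -2.17, and the call was lost for each of them except the shControl library of donor A (adjusted p from 0.0507 to 0.163).

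**Figure D1:**
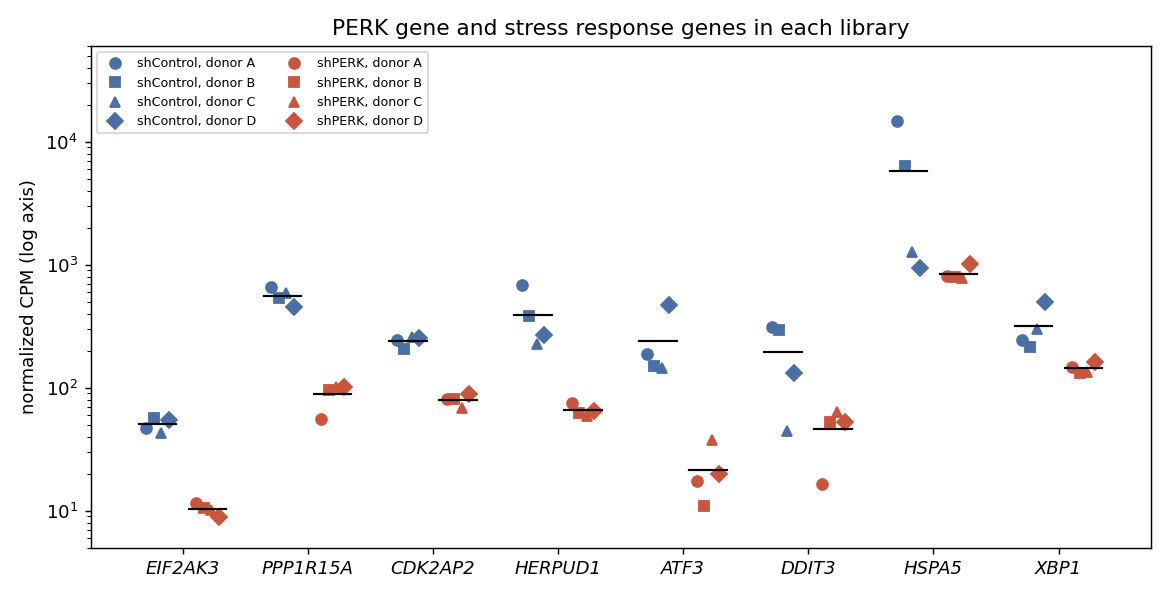
Normalized CPM on a log axis for 8 genes in each of the 8 libraries. Blue symbols are shControl and red symbols shPERK, the symbol shape gives the donor, and black bars are the arm means. EIF2AK3 lies between 42.7 and 56.8 in shControl and between 8.86 and 11.5 in shPERK, while HSPA5 is at 14592 and 6375 in the shControl libraries of donors A and B and between 780 and 1262 in the other 6 libraries.

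Transcripts of the unfolded protein response, which enlarges the folding capacity of the endoplasmic reticulum, fell as a group in shPERK. Of 33 chaperone and ER-associated degradation genes downstream of ATF6 and XBP1, 32 had lower means in shPERK, with a mean log2 difference of -1.20 (camera adjusted p = 2.96e-12; adjusted p = 0.55 with an estimated correlation). None of the 33 passed the limma test over all genes (0, against 20 lower at an unadjusted p under 0.05), and 17 were lower adjusted over the list alone. DNAJB9, an ER co-chaperone, was at 221 ± 123 normalized CPM in shControl and 25.6 ± 9.23 in shPERK (log2 difference -2.97, adjusted p = 0.0611). HERPUD1, which acts in ER-associated degradation, was at 389 ± 205 and 65.4 ± 6.69 (-2.44, 0.0525). CRELD2, an ER stress-induced protein, was at 94.4 ± 20.7 and 32.4 ± 6.72 (-1.52, 0.0611). HSPA5, the main ER chaperone, stood at 14592 and 6375 in the shControl libraries of donors A and B, at 1262 and 933 in those of donors C and D, and between 780 and 1003 in shPERK (-1.94, 0.241). XBP1, a transcription factor of this response, had a log2 difference of -1.05 (adjusted p = 0.108).

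Genes of the integrated stress response, the programme of ATF4 downstream of eIF2α phosphorylation, also had lower means as a group. The fall of the list mean lay in donors A and B. Of the 48 fixed members 36 were tested, with no aminoacyl-tRNA synthetase among them. Of these 36 members, 28 had lower means in shPERK, with a mean log2 difference of -0.68 (camera adjusted p = 8.8e-07; adjusted p = 0.55 with an estimated correlation). One gene, PPP1R15A, passed over all genes (log2 difference -2.68, SE 0.26, adjusted p = 0.0217), and 12 were lower adjusted over the list alone. ATF3, a stress-induced transcription factor, was at 237 ± 155 in shControl and 21.4 ± 11.4 in shPERK (-3.39, 0.0525). SLC3A2, the heavy chain of amino acid transporters, was at 681 ± 117 and 242 ± 13.3 (-1.48, 0.0525). DDIT3, which encodes CHOP, had a log2 difference of -1.87 (adjusted p = 0.188) and ATF4 itself one of -0.90 (0.30). The list mean in donors A to D was 7.09, 7.33, 6.21 and 5.88 in shControl and 5.58, 6.01, 6.26 and 5.95 in shPERK. It was thus not lower in shPERK in donors C and D. In all 4 donors, 17 of the 36 members were lower and 1 was higher. The shControl libraries of donors A and B were also the 2 shControl libraries with high levels of mesenchymal and myeloid markers. The labels name myeloid, endothelial and tumour cells in the culture, and which cells gave the mesenchymal markers was not tested. Without them the chaperone list stayed lower in shPERK (mean log2 difference -0.53, camera adjusted p = 0.00327), and the integrated stress response list did not pass (-0.10, 0.0501). The shControl libraries left in that fit, of donors C and D, had low levels of mesenchymal and myeloid markers. Limma called 2893 genes higher and 1496 lower there. The fit therefore cannot tell a difference in the stress response from a difference in cell content.

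Over all 13450 genes tested, 7 were higher and 3 lower in shPERK (limma, adjusted p under 0.05), and 2738 had an unadjusted p under 0.05. With the donor as a block limma called 0 genes, with 2369 at an unadjusted p under 0.05, and each of the 10 genes had an adjusted p of 0.146. Among the named genes the largest log2 differences past the threshold were 5.08 for CD248 (SE 0.59, adjusted p = 0.0315), 4.42 for NRGN (SE 0.48, 0.026) and 3.92 for ENG (SE 0.47, 0.0341). TUBA1A differed by 2.16 (SE 0.22, 0.0217), MARCKSL1 by 2.13 (SE 0.22, 0.0217) and CDK2AP2 by -1.58 (SE 0.18, 0.0265). Each of these genes moved the same way in all 4 donors. CD248 and NRGN lie on chromosome 11 at 66314487 to 66317044 and 124739846 to 124747210, ENG on chromosome 9 at 127815012 to 127854756, and PPP1R15A on chromosome 19 at 48872392 to 48876057. The other 2 higher genes fell outside the rule for named genes and are named after their values were seen. ACOX2, a peroxisomal oxidase, rose by 2.99 (adjusted p = 0.0315), and AL022067.1, an RNA from an intron of PRDM1, was at the lowest value in the files in all 4 shControl libraries and between 6.23 and 7.74 normalized CPM in shPERK (adjusted p = 0.00682). Among genes that did not pass, CD93, a myeloid and endothelial surface protein, had a log2 difference of 3.94 (adjusted p = 0.119), CD83, an activation marker, of -2.85 (0.0718), and HIVEP2, a zinc finger transcription factor, of -2.35 (0.0525). Leaving out the shControl library of donor A raised the counts to 132 higher and 22 lower genes, and leaving out any 1 of the other 7 libraries gave at most 6 higher and 2 lower. All 8 named genes past the threshold lost it without the shControl library of donor C (adjusted p from 0.0653 to 0.122) or without the shPERK library of donor B (0.163), C (0.0838 to 0.0971) or D (0.0519 to 0.101). Without the shPERK library of donor A (0.0735 to 0.103) or the shControl library of donor D (0.0519) 7 of them lost it, all but PPP1R15A, and without the shControl library of donor B 3 did (0.0507 to 0.0518).

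Markers of the other cells in the culture were higher in shPERK, and they varied widely between libraries of 1 arm. All 20 myeloid markers had higher values in shPERK in each of the 4 donors, with a mean log2 difference of 3.96 (camera adjusted p = 4.98e-10; adjusted p = 0.55 with an estimated correlation). None of the 20 passed over all genes in limma (0, against 17 higher at an unadjusted p under 0.05), and 15 were higher adjusted over the list alone. VSIG4, a macrophage complement receptor, was at 6.05 ± 10.8 in shControl and 308 ± 299 in shPERK (adjusted p = 0.079). CSF1R, the receptor for the macrophage growth factor CSF1, was at 1.39 ± 0.465 and 11.7 ± 7.69 (0.079). MRC1, the macrophage mannose receptor, was at 5.65 ± 8.16 and 182 ± 188 (0.0851). All 13 mesenchymal markers had higher means in shPERK, by 3.74 log2 units on average (camera adjusted p = 0.000132; adjusted p = 0.565 with an estimated correlation). So did all 5 endothelial markers tested, by 1.85 (0.00642; adjusted p = 0.55 with an estimated correlation), and all 8 epithelial markers tested, by 2.05 (0.0257; adjusted p = 0.591 with an estimated correlation). Of endothelial markers 15 had been fixed and of epithelial markers 16. VWF, CDH5 and KDR of the former and EPCAM, KRT19 and CDH1 of the latter were not among those tested. Adjusted over the list alone, 3 endothelial, 0 mesenchymal and 0 epithelial markers were higher. Over all genes 1, ENG, passed in limma, while 5 mesenchymal and 2 epithelial markers had an unadjusted p under 0.05. THY1, a fibroblast surface protein, was at 44.1 ± 52.7 in shControl and 505 ± 213 in shPERK (adjusted p = 0.129). KRT18, an epithelial keratin, was at 40.2 ± 45.4 and 181 ± 91.6 (0.211).

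T cell transcripts differed widely between libraries of the same arm. CD3E, a subunit of the CD3 complex chosen here after its values were seen, stood at 34.3, 16.8, 706 and 568 normalized CPM in the shControl libraries of donors A to D and at 167, 102, 5.78 and 13.6 in the shPERK libraries. COL1A1, a collagen chain and mesenchymal marker, stood at 2630, 307, 0.376 and 1.84 in shControl and at 4143, 2450, 2808 and 3030 in shPERK (log2 difference 6.41, adjusted p = 0.191). The shControl libraries of donors C and D, which had the highest CD3E, were the only 2 of the 8 with COL1A1 under 10 normalized CPM. Without these 2 libraries, a choice made after seeing the data, the mesenchymal list was higher in shPERK by 0.83 log2 units (camera adjusted p = 0.04) and the myeloid list by 2.03 (3.71e-05), while the endothelial list (0.85, 0.113; 3 of 5 markers higher) and the epithelial list (-0.44, 0.505) did not pass. Leaving out the shControl library of donor C or of donor D alone also ended the epithelial call (adjusted p = 0.113 and 0.129).

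**Figure D2:**
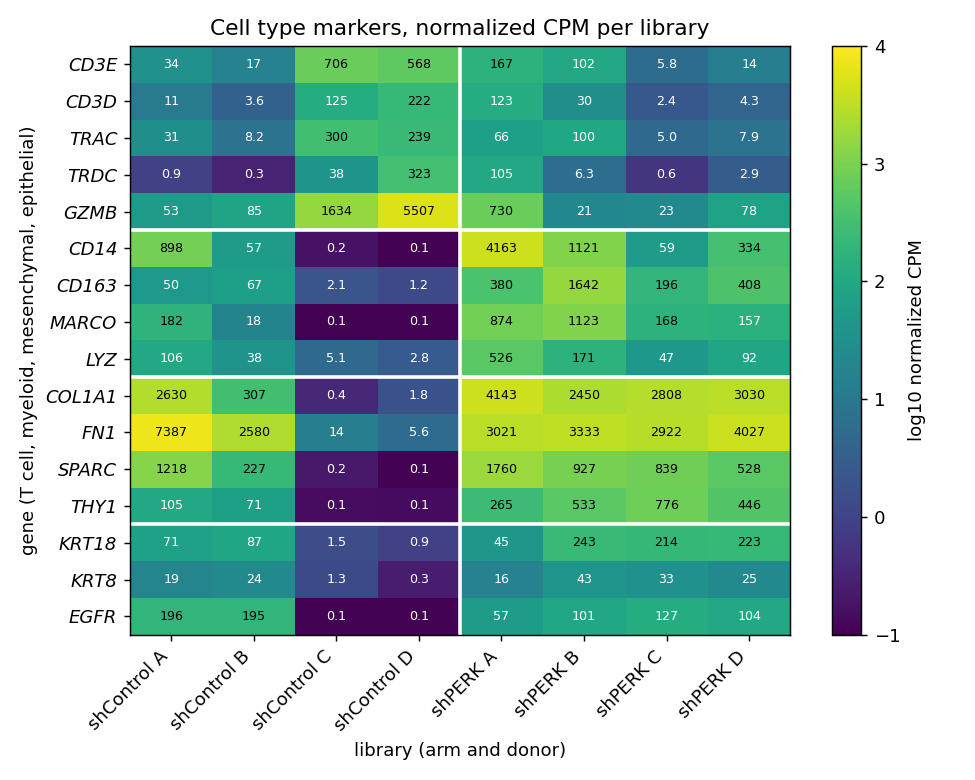
Normalized CPM of 16 marker genes of T cells, myeloid, mesenchymal and epithelial cells (rows, in that order, parted by white lines) in the 8 libraries (columns), with colour on a log10 scale and the value printed in each cell. In the shControl libraries of donors C and D, CD3E is at 706 and 568 and COL1A1 at 0.376 and 1.84, while COL1A1 is between 307 and 4143 in the other 6 libraries.

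Genes of T cell activation had lower means as a group in shPERK, a fall that lay in donors C and D. Of 20 activation, costimulation and cytokine receptor genes, 18 had lower means in shPERK, by 1.80 log2 units over the list (mean -1.80, camera adjusted p = 5.54e-05; adjusted p = 0.55 with an estimated correlation). Of 20 inhibitory receptor and dysfunction genes, 18 had lower means (-1.51, 0.00317; adjusted p = 0.591 with an estimated correlation). The activation list mean in donors A to D was 4.97, 4.14, 6.86 and 7.64 in shControl and 4.95, 4.25, 3.39 and 3.83 in shPERK. The inhibitory list mean was 3.20, 2.46, 5.58 and 6.60 in shControl and 4.24, 2.94, 2.06 and 2.57 in shPERK, so higher in shPERK in donors A and B. None of either list passed over all genes in limma (0, against 5 and 4 lower at an unadjusted p under 0.05), and 1 and 0 were lower adjusted over the list alone. IRF4, a transcription factor induced by receptor signalling, was at 318 ± 327 in shControl and 8.37 ± 9.81 in shPERK (adjusted p = 0.14). PRDM1, a regulator of effector differentiation, was at 89.0 ± 91.0 and 18.7 ± 8.35 (0.157), and NR4A2, an orphan nuclear receptor, at 171 ± 250 and 6.16 ± 8.27 (0.195). IFNG, the gene of interferon-γ, stood at 1064 and 6274 normalized CPM in the shControl libraries of donors C and D, at 8.999 and 5.05 in those of donors A and B, and between 0.286 and 4.11 in shPERK (log2 difference -6.15, adjusted p = 0.181). Cytotoxic effectors (mean -1.21, camera adjusted p = 0.0532), memory-associated genes (-0.90, 0.0599), cytokines and chemokines (-0.91, 0.0891), γδ T cell identity genes (-0.58, 0.395) and αβ T cell markers (-1.44, 0.0737) did not pass as lists. In donors A and B the identity list was higher in shPERK and in donors C and D lower. This list holds the 8 genes of the T cell score, which are not particular to γδ T cells. It therefore also follows the T cell content of a library. With the donor as a block, cytotoxic effectors (adjusted p = 0.0443; adjusted p = 0.656 with an estimated correlation) and cytokines and chemokines (0.0443; adjusted p = 0.511 with an estimated correlation) passed, both with lower means in shPERK over the 4 donors. The cytotoxic mean was higher in shPERK in donors A (6.18 against 3.01) and B (3.47 against 2.36). Without the shControl libraries of donors C and D neither the activation list (-0.45, 0.305) nor the inhibitory list (0.12, 0.995) passed. With the T cell score (mean log2 level of 8 T cell genes) as a covariate, also chosen after seeing the data, both stayed lower in shPERK (-1.25, camera adjusted p = 7.87e-06, and -0.83, 0.00656). Leaving out the shControl library of donor D alone ended the call of the inhibitory list (adjusted p = 0.0649).

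Mitochondrial and metabolic transcripts rose as groups in shPERK. All 13 messenger RNAs of the mitochondrial genome had higher means, by 1.15 log2 units on average (camera adjusted p = 0.00119; adjusted p = 0.591 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, was at 3028 ± 1304 in shControl and 9049 ± 4618 in shPERK (adjusted p = 0.201). Mitochondrial messenger RNAs took 14.05% and 10% of the normalized values in the shPERK libraries of donors C and D, the 2 shPERK libraries with the lowest CD3E. The share was 8.33% and 2.86% in those of donors A and B and 2.54% to 5.91% in shControl. Donor B showed no rise, with a share of 2.99% in shControl and a list mean of 10.349 in both arms. In all 4 donors, 6 of the 13 were higher in shPERK. Of 54 fixed nuclear genes of oxidative phosphorylation 42 were tested, with no ATP synthase subunit among them. Of these 42 genes, 35 had higher means (0.31, 0.00163; adjusted p = 0.591 with an estimated correlation). NDUFA4, a respiratory chain subunit, was at 86.6 ± 23.2 in shControl and 144 ± 17.3 in shPERK (adjusted p = 0.133). Of 23 glycolysis genes, 19 had higher means (0.71, 0.0031; adjusted p = 0.556 with an estimated correlation). PKM, the pyruvate kinase gene, was at 2518 ± 400 and 5676 ± 1052 (0.147), and SLC16A3, a lactate exporter, at 283 ± 275 and 843 ± 337 (0.201). Genes of the tricarboxylic acid cycle and fatty acid oxidation (19 of 25 higher, mean 0.25, camera adjusted p = 0.0487; adjusted p = 0.591 with an estimated correlation) and antioxidant genes under NRF2 (21 of 29 higher, 0.43, 0.0367; adjusted p = 0.55 with an estimated correlation) were near the threshold. No gene of these 5 lists passed in limma over all genes or adjusted over the list alone (0, against 2, 5, 5, 4 and 7 higher at an unadjusted p under 0.05, in the order given). The glycolysis mean was lowest in the shControl libraries of donors C and D (7.42 and 7.74, against 8.42 to 8.88 elsewhere), and without these 2 libraries the list did not pass (0.18, 0.247). Leaving out the shControl library of donor A ended the call of the oxidative phosphorylation list (adjusted p = 0.0667), the antioxidant list (0.129) and the tricarboxylic acid cycle list (0.249). The last was also lost without the shControl library of donor B (0.0613) or the shPERK library of donor C (0.15) or D (0.0537), and the antioxidant list without the shControl library (0.0837) or the shPERK library (0.0699) of donor D. Without both shControl libraries of donors A and B the oxidative phosphorylation (0.14, camera adjusted p = 0.71), tricarboxylic acid cycle (0.16, 0.665) and antioxidant lists (0.71, 0.138) did not pass. Without those of donors C and D the antioxidant list did not pass (0.16, 0.109), while the other 2 did (0.49, 4.05e-07, and 0.34, 0.0206). With the T cell score as a covariate the tricarboxylic acid cycle list did not pass (0.25, 0.0748).

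Cell cycle and hypoxia lists passed in the comparison of all 8 libraries, and their direction depended on which shControl libraries entered. Of 35 cell cycle genes, 31 had higher means in shPERK (mean 0.74, camera adjusted p = 0.0054; adjusted p = 0.593 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, was at 92.7 ± 49.0 and 297 ± 89.0 (adjusted p = 0.096). Without the shControl libraries of donors A and B the list was lower in shPERK (-0.44, 0.0225), and without those of donors C and D it was higher (1.91, 4.21e-18). Leaving out the shControl library of donor A (0.0645) or B (0.504) alone ended the call. Of 23 hypoxia genes, 18 had higher means in shPERK (1.31, 0.0367; adjusted p = 0.593 with an estimated correlation). CA9, a hypoxia-induced carbonic anhydrase, was at 110 and 192 in the shControl libraries of donors A and B, at the lowest value in the files in those of donors C and D, and between 173 and 433 in shPERK (adjusted p = 0.219). Without the shControl libraries of donors C and D the hypoxia list was lower in shPERK (-0.40, 0.04). It did not pass without either of them alone (0.24 and 0.292) or without the shPERK library of donor D (0.0699). With the T cell score as a covariate it did not pass either (0.78, camera adjusted p = 0.127). Of 35 interferon-stimulated genes, 26 had lower means (-0.38, 0.0257; adjusted p = 0.593 with an estimated correlation). IFIT2, an interferon-induced antiviral protein, was at 17.5 ± 6.09 and 3.67 ± 3.88 (0.135). Leaving out the shControl library of donor B or the shPERK library of donor A ended that call (0.129 and 0.521). No gene of these 3 lists passed in limma over all genes or over the list alone (0, against 8 cell cycle and 3 hypoxia genes higher and 5 interferon-stimulated genes lower at an unadjusted p under 0.05).

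The remaining lists did not pass. They were NF-κB targets (mean -0.27, camera adjusted p = 0.0645), immediate early and heat shock genes (0.45, 0.0693), apoptosis and p53 genes (-0.23, 0.0761), genes of cholesterol synthesis (-0.21, 0.13), cytosolic ribosomal proteins (-0.10, 0.237) and genes of mitochondrial biogenesis and turnover, whose mean (0.07) and test (lower, 0.505) differed in sign. With the donor as a block NF-κB targets passed, lower in shPERK (adjusted p = 0.0343; adjusted p = 0.631 with an estimated correlation). Adjusted over the list alone, 4 NF-κB targets were lower, and 4 cholesterol genes were lower and 1 higher. The cholesterol list passed fry's test of change in either direction (adjusted p = 0.000538), as did the integrated stress response (3.08e-05) and chaperone lists (0.00514). STARD4, a sterol carrier, was at 79.7 ± 27.5 in shControl and 21.9 ± 2.55 in shPERK (adjusted p = 0.0585), and TRAF1, an NF-κB target and signalling adaptor, at 263 ± 134 and 48.2 ± 22.4 (0.0784). HSPB1, a small heat shock protein, was at 112 ± 118 and 1012 ± 513 (0.0932), and YME1L1, a mitochondrial protease, at 274 ± 25.0 and 142 ± 15.8 (0.0638). B cell markers (3 measured, mean -0.92) and natural killer cell markers (4 measured, mean 0.10 and median -0.67) were too few to test, and no erythroid or platelet marker was measured.

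**Figure D3:**
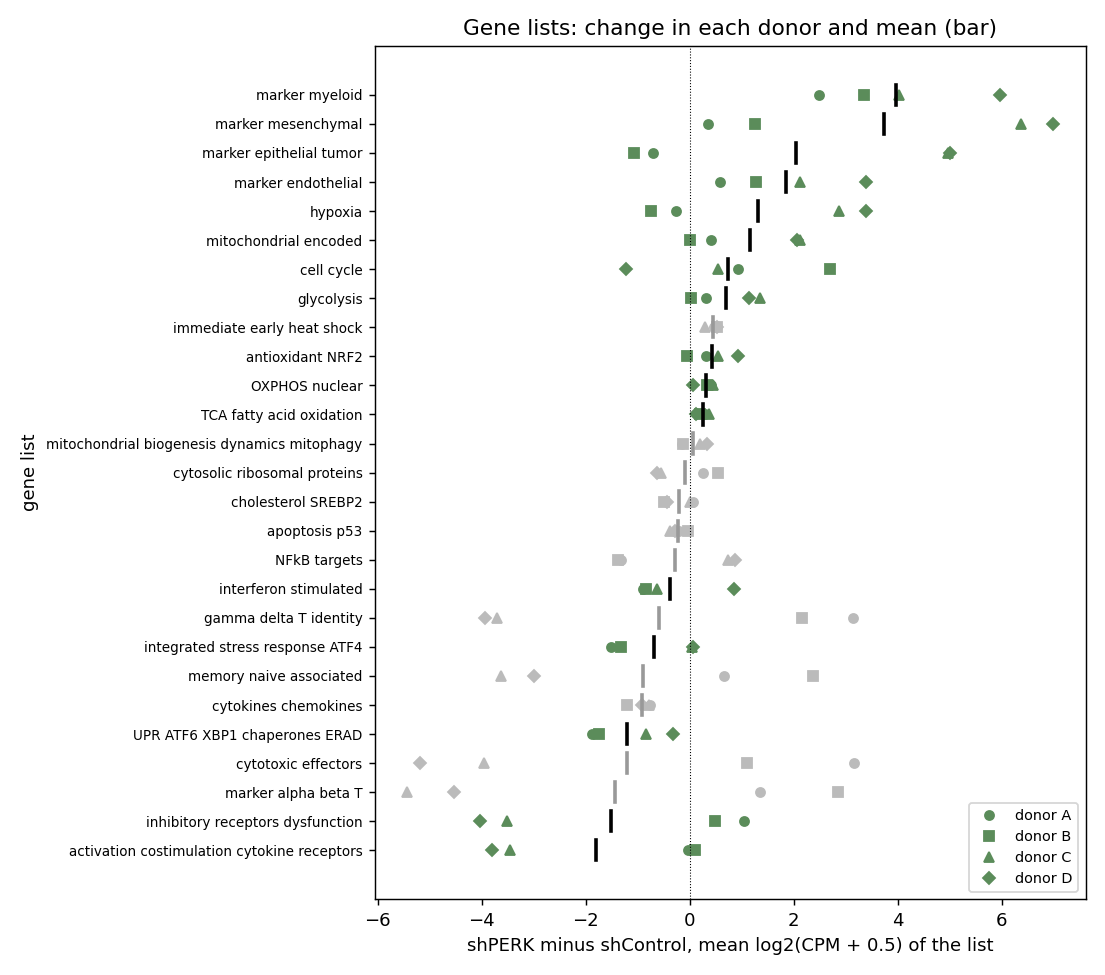
Mean of log2(CPM + 0.5) over each of the 27 gene lists tested, shPERK minus shControl, with 1 symbol per donor and a bar at the mean of the 4 donors. Green symbols with black bars are lists past the camera threshold and grey ones are not. The chaperone list is below 0 in all 4 donors and the myeloid list above 0 in all 4, whereas several T cell lists are above 0 in donors A and B and below 0 in donors C and D.

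With the donor as a block, camera called all 16 lists named above as passing at the preset correlation and 0 of the 27 lists with an estimated correlation (smallest adjusted p = 0.511).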

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

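Of the tests in this part, those on the T cell transcripts, the range of EIF2AK3 within shControl, EIF2AK3 in the libraries with few T cell transcripts, the marker lists without the shControl libraries of donors C and D, the stress genes with the T cell score as a covariate, and the stress genes of donors C and D (including the spread their gaps were set against and the parting by list) were chosen after the results were seen.

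T cell transcripts differed between libraries of the same arm, with a T cell score (mean log2 level of 8 T cell genes) of 3.51, 2.24, 7.01 and 7.88 in the shControl libraries of donors A to D and 6.30, 5.39, 1.60 and 2.70 in shPERK. The tables argue against the authors' scaling, since the mesenchymal mean moved by -7.55 log2 units from the library with the lowest to the one with the highest score, and against an exchange of libraries between the arms, since the lowest shControl value of EIF2AK3 was 3.73 times the highest shPERK value. RNA from other cells of the co-culture, which the CD3 beads should remove, may be a source, since the mesenchymal mean of the 6 libraries with the lower scores lay at least 4.35 log2 units above that of the shControl libraries of donors C and D. Within these 6 the mesenchymal mean did not fall as the score rose. It was 8.44 in the shPERK library of donor A (score 6.30) and 6.35 in the shControl library of donor B (2.24). FN1 reached 7387 and COL1A1 4143 normalized CPM in single libraries, while in the shControl libraries of both donors C and D only 6 of 13 mesenchymal and 7 of 20 myeloid markers reached 1 normalized CPM, 0 of either reached 10, and 0 of either is in another list. An effect of the hairpin on T cell recovery stays open and untested, and the score was higher in shPERK in donors A and B and lower in donors C and D.

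EIF2AK3 was lower in all 4 shPERK libraries than in any shControl library. The tables argue against the share of RNA of other cells as the cause, because the shControl libraries, whose T cell scores span nearly the whole range, differed at most 1.33-fold in EIF2AK3. They also argue against a shared movement with the other unfolded protein response genes, which left a log2 difference of -2.19 (SE 0.205) with the chaperone list as a covariate. A knockdown in T cells only was tested in the 4 libraries with the lowest T cell scores. The test holds only if both arms had the same kinds of other cells. There the lower of the shControl values of donors A and B was 4.64 times the higher of the shPERK values of donors C and D, above that 1.33. This cannot decide the question, since other transcripts differed between these libraries and the condition cannot be taken as met. GFAP was at 4.35 and 3.11 in shControl and 126 and 20.8 in shPERK, TUBB3 at 26.1 and 11.7 against 149 and 94.3. EGFR was lower in shPERK (196 and 195 against 127 and 104). These genes were chosen after their values were seen. The kind of other cells stays open, since without the shControl libraries of donors C and D the myeloid list was higher in shPERK by 2.03 log2 units (camera adjusted p = 3.71e-05) and the epithelial list at -0.44 (0.505), and no table shows which cells carried the hairpin.

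Stress response genes were lower in shPERK, with a mean over 69 genes of the integrated stress response and chaperone lists of 7.74, 7.84, 6.70 and 6.39 in the shControl libraries of donors A to D and 6.05, 6.32, 6.32 and 6.26 in shPERK. With the T cell score as a covariate the difference was -1.13 (SE 0.237), so the score with 1 slope for both arms does not account for all of it. The slopes looked unlike, which limits this fit. In shControl the mean was 7.84 at a score of 2.24 and 6.39 at 7.88. In shPERK it lay between 6.05 and 6.32 over scores of 1.60 to 6.30. Whether the shControl libraries of donors A and B alone were high was left open by the 2 lists together, where the gap from the lower shControl value of donors C and D to the highest shPERK value was 0.07 (SD of the shPERK libraries 0.127), and the lists were then parted. For the chaperone list the tables argue against it, since the gap was 0.28 (SD 0.12), whereas for the integrated stress response list it was -0.38 (SD 0.282), so its mean in those donors gives no difference beyond these 2 libraries, although PPP1R15A and ATF3 were lower in shPERK in all 4 donors. The shControl libraries of donors C and D had mesenchymal means of 1.99 and 0.81, against 7.60 to 8.44 in shPERK. What the chaperone gap reflects therefore cannot be told apart from a difference in cell content. Lower PERK signalling may contribute, and a higher level of ER stress in the 2 co-cultures of shControl donors A and B stays open and was not measured.

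Other splits of the 8 libraries into 4 and 4 bear on the counts. Of 35 splits, 2 gave at least the 10 genes of the real one, and the highest of the others gave 100, so chance cannot be excluded. That split set the shControl libraries of donors A and B with the shPERK libraries of donors C and D, which have the lowest T cell scores, against the rest, and it points to a structure of the samples. It parts all 4 donor pairs, as do 8 splits in all, and the other 6 of these gave 0 genes in limma. For gene lists, 11 of 35 splits gave at least the 16 lists of the real one and the highest of the others gave 20, so chance cannot be excluded there either.

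Single libraries stood far from the other 3 of their arm in 10 of 262 groups tested, where chance gives about 1 in 20. Values are log2(CPM + 0.5). In the shPERK library of donor A, DDIT3 was at 4.07 (others 5.735 to 5.985), NRGN at 5.72 (6.398 to 6.506), PPP1R15A at 5.81 (6.59 to 6.674), BAG3 at 6.04 (6.272 to 6.294) and KRT18 at 5.52 (7.743 to 7.929), all below the others. In the shPERK library of donor B, EIF2AK1 was at 8.12, above the others (7.667 to 7.726), and SLAMF7 at 4.33 (6.937 to 7.231) and TP53I3 at 3.001 (4.008 to 4.191) were below them. MMRN2 was at 3.54 in the shPERK library of donor C (others 1.966 to 2.215), and PKM at 10.91 in the shControl library of donor C (others 11.38 to 11.44).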

How the results depend on the processing

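The tests without the shControl libraries of 2 donors and with the T cell score as a covariate were chosen after seeing the data. The log2 difference of EIF2AK3 lay between -2.40 and -2.09 in 32 other settings and passed in 15 of them (adjusted p from 0.00124 to 0.497). It did not pass with the donor as a block (-2.24, 0.146), with the block and quantile normalization (-2.40, 0.121), or in most fits that left out libraries (-2.3189 to -2.134). The block reduces the residual degrees of freedom, and the cause of the lost calls was not tested further. Quantile normalization moved the median difference of all genes from 0.02 to -0.13, so changes are relative to that shift. Depth is unknown, and its limit on low genes could not be assessed.

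Against 7 genes higher and 3 lower, 0 and 0 were called by limma with the donor as a block (2369 at an unadjusted p under 0.05) and 0 and 0 with the block and quantile normalization (2737). A pseudocount of 2 gave 27 and 14, quantile normalization 16 and 10, array weights 139 and 167 (45.4% higher, against 70%), the deposited log2 values 4 higher (57.1%) and moderation without the trend 11 higher (84.6%, against 70%). The share of higher calls was 62.5% at a pseudocount of 0.1, 65.9% at 2, 61.5% with quantile normalization and 63.6% with median centring. Leaving out libraries or donors gave 0 to 132 higher and 0 to 22 lower. Without the shControl libraries of donors C and D, 390 and 441 genes were called, without those of donors A and B 2893 and 1496, and with the T cell score as a covariate 97 and 67. All 10 calls remained in each of these 3 fits. The donor as a random effect was run for genes only, and count models were not run.

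Against 11 lists higher and 5 lower, 0 and 0 were called with an estimated correlation and 0 and 0 by fry (smallest adjusted p 0.0815). An estimated correlation above the preset 0.01 widens the error of a list's mean. The apoptosis list had an estimated correlation of -0.022, and its camera adjusted p still went from 0.0761 to 0.55. The cause of the lost calls was not tested for camera or for fry. Its test of change in either direction, not among the tests fixed beforehand, called the integrated stress response (adjusted p = 3.08e-05), chaperone (0.00514) and cholesterol lists (0.000538). With the donor as a block 8 lists were lower, and it changed no other list call than those of cytotoxic, cytokine and NF-κB genes. Leaving out libraries or donors gave 7 to 11 higher and 4 to 10 lower, and leaving out the shControl libraries of donors A and B gave 7 and 9.

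Some differences changed sign, and the cause was not tested. Without the shControl libraries of donors A and B, EIF2AK1 was at 0.55 and the cell cycle list at -0.44. Without those of donors C and D, CD22 was at 0.11, CD7 at 0.38, CD79A at 1.62, CD79B at 1.0189, IL2RB at 0.20, RPS12 at 0.04 (0.0444) and TRAC at 0.51, and the lists were at 0.36 for ribosomal proteins, 1.08 for cytotoxic, 1.28 for γδ identity, -0.40 for hypoxia, 0.12 for inhibitory, 0.54 for αβ T, -0.44 (-0.4368) for epithelial and 0.37 for memory genes. With array weights CD79A was at 0.48, the ribosomal list at 0.20 and the identity list, whose mean and test differed in sign there, at -0.01 (-0.0103). With the T cell score as a covariate the ribosomal list was at 0.04 (0.0409) and the identity list at 0.34. Leaving out libraries or donors gave ranges of -0.2472 to 0.2241 for EIF2AK1, -2.287 to 0.1712 for CD7, -2.0504 to 1.0351 for CD79A, -2.0924 to 0.3246 for CD79B, -0.3124 to 0.0857 for the ribosomal, -2.6737 to 0.1073 for the cytotoxic and -1.8253 to 0.536 for the identity list.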

Other observations

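The most abundant transcripts differed between libraries, and the genes in this part were chosen after their values were seen. In the shControl library of donor D, CCL3, CCL4, IFNG and GZMB, genes of activated cytotoxic lymphocytes, stood at 7151, 6376, 6274 and 5507 normalized CPM, among the 6 highest genes of that library. In the shControl library of donor A, CXCL8, HSPA5, PTGS2, FN1 and IL6 were among the 8 highest, at 17893, 14592, 9936, 7387 and 5626. CXCL5, a neutrophil chemokine, reached 24716 in the shPERK library of donor A and was at the lowest value in the files in the shControl libraries of donors C and D.

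GFAP, TUBB3 and SOX2 had higher means in shPERK and did not pass in limma. No list of their kind was tested. GFAP, a glial intermediate filament, was at 2.39 ± 1.66 normalized CPM in shControl and 73.8 ± 46.2 in shPERK (SD, n = 4, limma adjusted p = 0.0551), TUBB3, a neuronal tubulin, at 10.8 ± 11.1 and 186 ± 94.5 (0.0611), and SOX2, a transcription factor of neural progenitors, at 2.33 ± 3.92 and 37.5 ± 22.1 (0.0714). These were higher in shPERK in 4 of 4 donors. In the shControl libraries of donors A and B, which had COL1A1 at 2630 and 307, GFAP was at 4.35 and 3.11.

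Receptor constant chains were measured for both T cell lineages. TRDC, the δ chain, stood at 0.913, 0.32, 38.1 and 323 normalized CPM in the shControl libraries of donors A to D and at 105, 6.29, 0.595 and 2.92 in shPERK. TRAC, the α chain, stood at 31.3, 8.19, 299.9 and 239 in shControl and at 66.5, 100.2, 5.03 and 7.94 in shPERK. TRAC was above TRDC in 6 of the 8 libraries, and TRDC above TRAC in the shControl library of donor D and the shPERK library of donor A.

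AL022067.1, annotated as a sense intronic RNA on chromosome 6 at 106100140 to 106100593, lies inside PRDM1 (106086320 to 106109939). It was at the lowest value in the files in all 4 shControl libraries and at 6.23, 7.21, 7.74 and 6.66 normalized CPM in the shPERK libraries of donors A to D, whereas PRDM1 was at 89.0 ± 91.0 in shControl and 18.7 ± 8.35 in shPERK. No test of a cause was made.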
